A study of Mus musculus with 3 samples.

How the data were processed

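RNA was measured in CD4+ T cells labelled Th1 from wild-type C57/Bl6j mice aged 7 weeks, with 2 libraries from lymphoid organs and 1 from B16-F10 tumours. Per the labels' protocols, total RNA came from 300000 cells, and 12 µl of it was made into stranded libraries after ribosomal RNA removal and sequenced in pairs of 75 bp on a NextSeq 500. The submitters' processing notes name the mouse build mm10, kallisto and DESeq2, without versions or roles. The program that made the values, its annotation and any filter are not given in the sources used here.

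The deposited values were taken as FPKM, with 1 value for each of 23832 gene rows in each library. This unit is not stated and was inferred. Per the file headers the columns have the style of Cufflinks tables, and the deposited FPKM sums of 955281, 1175316 and 279397 differ between libraries, which TPM would not. Rows of small RNA genes held 80.9%, 83.2% and 67.3% of these sums. For 252 symbols with several rows the row with the highest mean was kept, which left 23337 symbols. Of these, 21705 matched GENCODE release M21 (GRCm38, the assembly of mm10) by symbol and 1271 by a unique older symbol, for coordinates, gene classes and transcript lengths. All 3 columns of values were assigned to a sample.

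Depth was estimated from the values. Among genes with 1 annotated transcript of at least 1000 nt and under 2 FPKM, the value of FPKM times length shared by the most genes (within 3%) was taken as that of 1 fragment. It was 87.8, 64.9 and 307.3, shared by 180, 243 and 191 genes, for estimated depths of 11390000, 15410000 and 3250000 fragments. As a measure of background, FPKM was averaged over 1419 odorant and vomeronasal receptor genes, and over the 1391 left without the 2% of highest mean. The genes used for the step and the 2% trim were chosen after values had been seen.

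The test, fixed before the data were examined for values of this kind, was limma 3.58.1 in R 4.3.3 with a mean-variance trend, on log2(FPKM + 1) of 9800 genes with a mean of at least 1 FPKM, with a term for tumour, Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05. The count test foreseen for counts was not used, since the values are not counts. The spread comes from the 2 lymphoid libraries, with 1 residual degree of freedom. Because most genes shifted together, median-of-ratios size factors (1.29, 1.33 and 0.58), foreseen as another scaling, were made a result of their own, and they carry the values for genes and lists in the text. Fold counts, which have no test, used the scaled values.

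Counting error was added in a further fit, chosen after seeing the data. To the squared SE it adds the Poisson variance of the tumour value, from its estimated fragments (at least 1), carried to the log scale, for 9714 tested genes with a transcript length. Its handling of genes without a length and of genes at 0 was changed after its first results had been seen. The first run left 371 higher and 95 lower calls, leaving genes without a length untested gave 351 and 94, and giving genes at 0 the error of 1 fragment gave the 325 and 29 reported. The scaled fit was tested on simulated data of 9800 genes with 200 changed. With log2 changes of 2, 98% were recovered with 11.8 false calls on average over 5 draws. With changes of 1, 0% were recovered, while the smallest called log2 change in the data was 0.55. In the data 21.9% of genes were called, and the Benjamini-Hochberg cutoff loosens as more genes are called. The simulation, with far fewer changed genes, therefore does not describe the calls of smaller changes. The simulated tumour library had the spread of the lymphoid ones and no added counting error, so false calls from low depth were not covered.

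The 35 gene lists were fixed before the data were examined. Lists with at least 3 tested members were tested with limma's camera (preset correlation 0.01, two-sided, adjusted over lists), and with an estimated correlation and fry. The estimated correlation rests on 1 residual degree of freedom, so that version has very little power. A call lost with it therefore cannot be read as evidence against the call. Camera sets a list against the other genes, so that a list it calls higher can still lie lower in the tumour library as deposited. List medians on scaled values were compared with 10000 random lists matched on mean expression. The rule for named genes was fixed at the same time. It took the 12 largest rises and 12 largest falls among genes called as deposited in the upper 50% of expression that moved the same way against both lymphoid libraries, without genes named only by clone or model and receptor variable segments. It also took the 2 largest called rises and falls of each list, or its most abundant member where none was called, both as deposited and after scaling, and 16 genes of interest. Genes picked later are said to be.

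Other settings were library totals, no filter, a mean of at least 5 FPKM, pseudocounts of 0.1 and 5, left-out gene classes, each lymphoid library left out, a minimum fold of 1.5, an adjusted p under 0.01, a fold of 3 and lists without shared members. Chosen after seeing the data were centring on the median gene, subtraction of the silent-gene mean, counting error, protein-coding genes with transcripts of at least 500 nt, removal of a trend with transcript length, no variance trend and a robust prior. Transcript usage was not analysed here, since each gene has 1 value.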

Results

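The series measured RNA from CD4+ T cells labelled Th1, the T helper subset defined by the transcription factor T-bet and by interferon gamma. The cells came from wild-type C57/Bl6j mice aged 7 weeks, either from lymphoid organs or from B16-F10 tumours, a transplantable melanoma line of the same mouse strain. The lymphoid group held 2 libraries, whose titles name spleen and whose tissue label names spleen, lymph nodes and draining lymph nodes together. The tumour group held 1 library. The series description states an interest in how the tumour environment affects alternative splicing and gene expression. The labels do not say whether the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical. Values were taken as FPKM (fragments per kilobase of transcript, scaled to the sequenced fragments) for 23832 gene rows, with 1 value per gene. Transcript usage therefore could not be compared, and splicing is covered here through the expression of splicing-factor genes only.

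The libraries differed in depth. From the smallest steps between low values, a depth of about 11390000 fragments was estimated for lymphoid library 1, 15410000 for lymphoid library 2 and 3250000 for the tumour library. At 1 FPKM, a 2 kb transcript then corresponded to 22.8, 30.8 and 6.5 fragments. The median tested gene rested on about 26.5 tumour fragments, and 20.2% of tested genes rested on fewer than 10. The lymphoid libraries were close to each other. Across 9800 tested genes the SD of their log2 ratio was 0.36, and Pearson's r across genes was 0.977 (Spearman's rho 0.968), where genes are not independent replicates. Against the tumour library the SDs were 0.79 and 0.81, with r of 0.883 and 0.881.

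Most genes were lower in the tumour library as deposited. The median log2 fold change of all tested genes was -0.96, and limma with Benjamini-Hochberg adjustment called 7620 genes lower and 465 higher in tumour than in lymphoid cells. After scaling by median-of-ratios factors (1.29, 1.33 and 0.58) the median was -0.01, and 1246 genes were higher and 899 lower. The share of calls that were higher thus went from 5.8% to 58.1%. Scaling by library totals instead gave a median of 0.67 and 4333 higher against 275 lower calls, a higher share of 94.0%. These totals are sums of FPKM, of which small RNA rows held 80.9%, 83.2% and 67.3%. This scaling therefore mostly follows those rows and is a poor guide to the other genes. Changes below are relative to the median gene, as log2 of scaled FPKM plus 1, which understates the change of low genes, and levels are scaled FPKM with the SD of the 2 lymphoid libraries. Of the higher calls, 465 were also higher as deposited, and all 899 lower calls were also lower as deposited. The scaling raised tumour values against lymphoid ones, so this overlap was largely fixed in advance and is no separate support. The fit has 1 residual degree of freedom and assumes that the single tumour library varies like the lymphoid ones. When the tumour library's estimated counting error was added to the spread, 325 higher and 29 lower calls were left. That kept 26.1% of higher and 3.2% of lower calls. The added error comes from the tumour fragments, and 55.6% of lower calls rested on fewer than 10, against 15.6% of higher ones. The fit is thus harder on falls, and its counts do not show that changes were mostly rises. For the gene lists, fixed before the data were examined, calls over all tested genes are given first, and the count adjusted over the list alone is given where it differs.

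Without a test, 615 genes were at least 2-fold higher and 276 at least 2-fold lower in the tumour library than in each lymphoid library, after scaling. Between the 2 lymphoid libraries, 69 genes differed by that fold in either direction.

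Genes of inhibitory receptors and chronic stimulation contained some of the strongest rises. The member Nr4a1 is also in the list of immediate-early and heat-shock genes, which tissue dissociation can raise. Of 23 tested members, 7 were higher and 1 was lower, with the same counts when adjusted over the list alone. Nr4a1, a nuclear receptor induced by T cell receptor signalling (ENSMUSG00000023034.7, chromosome 15, 101254269 to 101274795, GRCm38), rose from 2.25 ± 0.171 (SD, n = 2) to 29.0, a log2 change of 3.21 with SE 0.15 (limma adjusted p = 0.000486). Tigit, an inhibitory receptor (ENSMUSG00000071552.5, chromosome 16, 43648867 to 43664146), rose from 8.32 ± 0.374 to 70.7, by 2.94 with SE 0.17 (limma adjusted p = 0.000707). Nr4a3 rose by 2.66, the inhibitory receptor Lag3 by 2.47, Ctla4 by 1.58, Cd200 by 1.55 and Cd38 by 1.43, of which Nr4a3, Lag3 and Cd38 were picked after their values were seen. The call of Cd200 ended with counting error added (adjusted p = 0.0628). Ptger4, a prostaglandin E2 receptor, fell by 0.76, and that call also ended (adjusted p = 0.202). Pdcd1, which encodes PD-1, was at 1.84 ± 0.258 and 1.92 and was not called. By camera, which sets a list against the other genes, the list was higher as deposited (adjusted p = 0.00886). It was also higher with library totals (adjusted p = 0.0238, and 0.994 with an estimated correlation). Camera did not call it with median-of-ratios scaling (adjusted p = 0.155) or, as deposited, with an estimated correlation (adjusted p = 0.901). Here and below, the estimated correlation rests on 1 residual degree of freedom, so a call lost with it decides nothing. As deposited the list's median was -0.69, against -0.96 for all tested genes, so that higher there meant less low. Its median after median-of-ratios scaling was 0.08 and its mean 0.64, so that the rise sat in part of its members.

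Activation and costimulation genes had 8 higher and 0 lower calls among 30 tested members (9 higher adjusted over the list alone). Tnfsf11, which encodes RANKL, rose from 3.06 ± 0.300 to 15.8 (log2 change 2.05), and the costimulatory receptor genes Tnfrsf9 and Icos rose by 1.49 and 1.21. With counting error added, 2 of the calls were left. The list's median of 0.16 lay at the 99.5 percentile of expression-matched random lists, while camera did not call it after scaling (adjusted p = 0.118) and called it lower as deposited with no filter on low genes (adjusted p = 0.00261; adjusted p = 0.741 with an estimated correlation). Cd44 was at 24.7 ± 1.93 and 19.8, and was not called.

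Th1 genes did not move together. Of 23 tested members 2 were higher and 2 lower (3 and 3 adjusted over the list alone). Ifngr1, a chain of the interferon gamma receptor (ENSMUSG00000020009.13, chromosome 10, 19591949 to 19610229), rose from 34.4 ± 2.68 to 141.6, by 2.01 with SE 0.19 (limma adjusted p = 0.00228), and the transcription factor gene Bhlhe40 rose by 1.57. Ifng itself (ENSMUSG00000055170.4, chromosome 10, 118441046 to 118445892) was lower, at 12.4 ± 0.643 in lymphoid and 4.53 in tumour cells. Its log2 change of -1.28 (SE 0.16, limma adjusted p = 0.00535) rested on about 10 tumour fragments and was not called with counting error added (adjusted p = 0.216). The chemokine receptor gene Cxcr6 was lower by a log2 change of -0.85, with the same loss (adjusted p = 0.15). Tbx21, which encodes T-bet, was at 19.1 ± 1.53 and 12.9 and was not called (adjusted p = 0.0879). The 17 tested pan-T-cell genes had 0 calls. Cd4 was at 63.6 ± 6.05 and 73.9, Cd3e at 116.0 ± 14.3 and 111.3, and Cd3g at 201.6 ± 19.8 and 144.4.

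Treg genes, those of regulatory T cells, had 6 higher and 2 lower calls of 19 tested (the same adjusted over the list alone). The higher ones included Gzmb (2.64), Ctla4 (1.58) and Tnfrsf9 (1.49), which activated T cells of other kinds also express. Foxp3, the lineage regulator, was lower at 10.1 ± 1.70 and 5.08 (log2 change -0.86), as was Socs2 (-1.16), and neither was called with counting error added (adjusted p = 0.225 and 0.236). Cytotoxic granule genes had 3 higher and 2 lower calls of 17. Gzmb, which encodes granzyme B (ENSMUSG00000015437.5, chromosome 14, 56258838 to 56262260), rose from 0.998 ± 0.225 to 11.4 (limma adjusted p = 0.000883), and Fasl by 0.92. Perforin, Prf1, was lower by -0.63 and Cst7 by -0.70. The calls of Fasl, Prf1 and Cst7 ended with counting error added (adjusted p = 0.147, 0.444 and 0.508).

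Naive and lymphoid-homing genes had 2 higher (Treml2 and Id3) and 3 lower calls of 28 tested. The lower ones were led by Ccr9, a gut-homing chemokine receptor, at 7.22 ± 0.996 and 2.74 (log2 change -1.13), and Actn1 (-0.88), and 0 of the 5 calls were left with counting error added. Ccr7 (0.35 against lymphoid library 1 and 0.70 against lymphoid library 2) and Tcf7 (log2 change -0.31), classic genes of naive and central memory T cells, were not called. Th2 genes had 1 call of 5 (Il4ra, higher by 1.05), Th17 genes 1 higher (Tmem176b, 0.91) and 1 lower (Cxcr6) of 8 (2 and 1 adjusted over the list alone), and Tfh genes 3 higher of 11 (Cd200, Icos and Bcl6, the last picked after its values were seen). Of these calls Il4ra alone was left with counting error added.

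Genes of the TGF-beta response had 4 higher and 1 lower calls of 15. Tgif1 rose from 3.05 ± 0.194 to 20.3 (2.39), Skil by 1.83 and Pmepa1 by 1.77. Cd9 was lower (-1.13), a call that ended with counting error added (adjusted p = 0.369). Hypoxia-response genes had 7 higher and 1 lower of 19, and 2 of the higher ones were left with counting error added. Among them Cxcr4, a chemokine receptor (ENSMUSG00000045382.6, chromosome 1, 128588199 to 128592293), rose from 1.81 ± 0.327 to 30.2, by 3.48 with SE 0.17 (limma adjusted p = 0.000492), and Bhlhe40 rose by 1.57. Pdk1 was lower (-0.70) and, with Mxi1 (1.34), lost its call with counting error added (adjusted p = 0.235 and 0.112). Immediate-early and heat-shock genes, which tissue dissociation can raise, had 3 higher calls of 27 (Fosl2 by 4.50, Nr4a1 by 3.21 and Dusp5, picked after its values were seen, by 1.95), while Fos (-0.36 against lymphoid library 1 and -0.87 against lymphoid library 2) and Jun (-0.71 and -1.39) were not called. The medians of these 3 lists, 0.37, 0.32 and 0.17, lay at the 99.6, 99.4 and 99.8 percentiles of matched random lists, and camera after scaling called none of them (adjusted p = 0.118, 0.118 and 0.155). High percentiles were not particular to these lists. Treg genes lay at 99.4, and pan-T-cell genes, with 0 calls and a median of 0.055, at 95.6, while naive and lymphoid-homing genes lay at 48.2. As deposited, camera called the TGF-beta and immediate-early lists higher than other genes at a mean of at least 5 FPKM (adjusted p = 0.00502 each). With an estimated correlation these calls were lost (adjusted p = 0.997), and at a mean of at least 1 FPKM there were none (adjusted p = 0.119 and 0.355). At that lower filter the 2 medians as deposited were -0.68 and -0.88, against -0.96 for all tested genes.

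Interferon-stimulated genes moved both ways, with 10 higher and 4 lower calls of 52 (12 and 4 adjusted over the list alone). Socs3 rose by 1.51, Oasl2 by 1.41 and Gbp5, picked after its values were seen, by 1.36, while Ifi47 and Usp18 were lower (-0.95 and -0.94). The calls of Oasl2, Ifi47 and Usp18 ended with counting error added (adjusted p = 0.0517, 0.200 and 0.325). Proliferation genes had 4 higher and 2 lower of 19 (5 and 3 adjusted over the list alone). Tyms, which encodes thymidylate synthase, rose from 12.6 ± 1.20 to 67.6 (2.34), and Cdca8 rose by 2.39. The replication helicase genes Mcm5 and Mcm6 were lower (-0.68 and -0.60), without a call once counting error was added (adjusted p = 0.382 and 0.298). Mki67 was at 1.85 ± 0.342 and 1.67 and was not called. Unfolded protein and integrated stress genes had 3 higher of 21 (2 adjusted over the list alone), led by the amino acid transporter gene Slc7a5 (1.34, adjusted p = 0.0744 with counting error added), while Ddit3 was not called (-0.33 against lymphoid library 1 and -1.35 against lymphoid library 2).

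Oxidative phosphorylation genes were the one list that camera called after median-of-ratios scaling (lower, adjusted p = 0.0374; adjusted p = 0.978 with an estimated correlation). With library totals camera did not call it. Of 75 tested members 0 were higher and 12 lower (9 adjusted over the list alone), and the median was -0.21. Uqcr10, a subunit of respiratory complex III, was at 18.7 ± 0.287 and 2.91, on about 3 tumour fragments (adjusted p = 0.192 with counting error added). Ndufs5, a complex I subunit, was at 17.8 and 24.5 FPKM in the lymphoid libraries and under 1 estimated fragment in the tumour library, and the list's adjusted p was 0.069 without it. Of the 76 ribosomal protein genes 1 was called, Rpl30, also under 1 estimated tumour fragment. That list was lower as deposited (adjusted p = 0.00596) but not after scaling (adjusted p = 0.118) or with an estimated correlation (adjusted p = 0.901). Oxidative phosphorylation genes had the same adjusted p as deposited (0.00596), also lost with an estimated correlation (adjusted p = 0.901). Glycolysis genes had 2 higher (Pfkfb3 by 0.91 and Tpi1 by 0.65) and 1 lower (Pgk1, -0.67) of 17, and cholesterol and fatty acid synthesis genes 1 higher (Cyp51, 0.91) and 1 lower (Scd2, -0.67) of 24, with 0 calls adjusted over that list alone. With counting error added, 0 of the calls of these metabolic lists were left. The mitochondrially encoded list had 0 of its 13 genes among the rows used here. Fry's mixed test, which counts changes in either direction, called the Th1 and inhibitory receptor lists on scaled values (adjusted p = 0.0271 each). It also called the cytotoxic granule, glycolysis, TGF-beta, melanocyte, hypoxia-response, proliferation, immediate-early and activation lists (adjusted p from 0.0331 to 0.0414). It called no other list, was run without counting error, and does not set a list against the other genes.

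**Figure D1:**
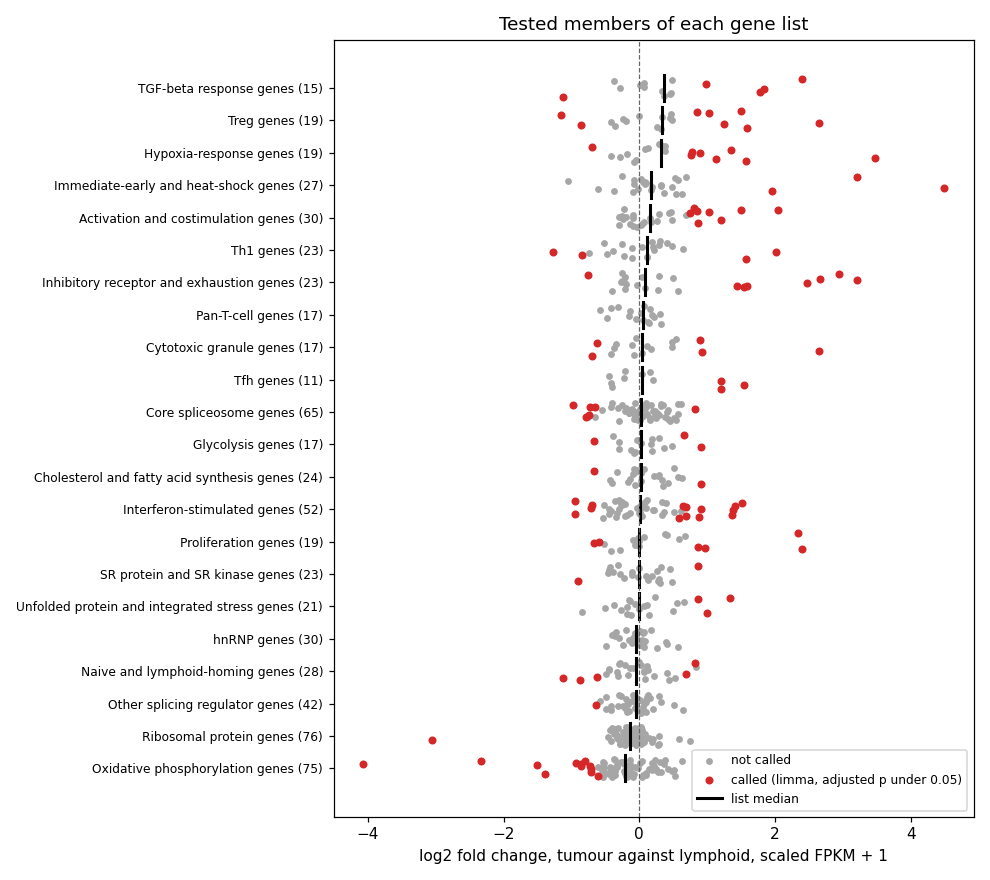
Log2 fold change of each tested member of the lists with at least 10 tested members, tumour against lymphoid, on scaled FPKM plus 1. Each point is a gene, red where limma called it, the bar is the list median and the number of tested members stands in brackets. Called genes lie on both sides of 0 in most lists, and the lowest median is that of the oxidative phosphorylation genes at -0.21.

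Few splicing-factor genes were called. Among 23 tested SR protein and SR kinase genes, Tra2a was higher (12.0 ± 1.51 and 22.7, log2 change 0.87) and Clk2, a kinase of SR proteins, was lower (12.4 ± 1.54 and 6.15, log2 change -0.91). Of 30 hnRNP genes 0 were called, and the abundant Hnrnpa2b1 was at 131.4 ± 10.9 and 111.1. Among 65 core spliceosome genes 1 was higher (Sf3b5, 0.82) and 5 were lower (Snrpe by a log2 change of -0.98, Lsm3 -0.78, Plrg1 -0.74, Snrpb -0.72 and Snrpa -0.66, the last 3 picked after their values were seen), and 0 were called when adjusted over the list alone. Among 42 other splicing regulator genes Mbnl3 was lower (-0.63), also not called over the list alone. The medians of the 4 lists were 0.00, -0.04, 0.03 and -0.05. With counting error added 0 splicing-factor genes were called. Camera called none of the 4 lists, either as deposited (adjusted p from 0.0854 to 0.263) or after scaling (adjusted p from 0.555 to 0.949). As deposited with no filter on low genes it called all 4 lower (adjusted p from 6.2e-06 to 0.000392), and with a pseudocount of 5 it called the hnRNP and other splicing regulator lists lower (adjusted p = 0.0209 each). With an estimated correlation these calls were lost (adjusted p = 0.741 with no filter and 0.895 with a pseudocount of 5).

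Genes of other cell types were mostly too low to test. Of 25 melanocyte and melanoma genes 4 were tested. Pmel was at 1.03, 1.11 and 0.861 FPKM as deposited in lymphoid libraries 1 and 2 and in the tumour library, and at 0.817 ± 0.0263 and 1.49 after scaling (log2 change 0.45, adjusted p = 0.105), and Mlana was listed at 0 in all 3. Gjc3 (2.22) and Ednrb (1.62) were higher (and Pmel, as the third gene, when adjusted over the list alone), and camera called the 4 genes higher as deposited (adjusted p = 0.00596) but not after scaling (adjusted p = 0.118) or with an estimated correlation (adjusted p = 0.901). Of 32 macrophage and monocyte genes 5 were tested, with Cx3cr1 (2.65) and Itgam (1.43) higher, while Lyz2 was at 0, 0.0648 and 0.303 FPKM. Of 24 B cell genes 5 were tested and Cd22 was higher (1.43), while Cd79a was at 0.137, 0.201 and 0 FPKM. Of 19 CD8 T cell and NK cell genes 5 were tested and Cd8b1 was higher (1.82; 1 higher and 1 lower adjusted over the list alone), while Cd8a was at 0.0837, 0.0406 and 0.292 FPKM. Eaf2 was the 1 call among 3 tested plasma cell genes (2.12), Cxcr2 the 1 call among 2 tested neutrophil genes (1.65), and Timp2 the 1 call among 2 fibroblast and stromal genes (-0.75). Dendritic cell genes had 0 calls of 4 and endothelial genes 0 of 1. Of 2 erythroid genes Bpgm was higher (1.27), and Hba-a1 was lower and listed at 0 in the tumour library. With counting error added, Gjc3, Cx3cr1, Cd22 and Eaf2 kept their calls and the other calls in these lists ended.

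**Figure D2:**
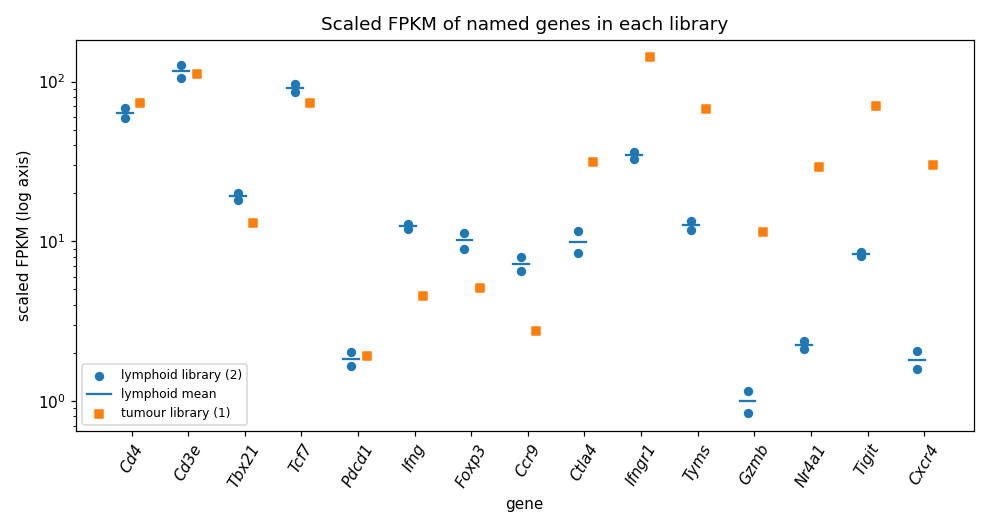
Scaled FPKM of 15 named genes in the 2 lymphoid libraries (circles, with a bar at their mean) and the tumour library (squares), on a log axis. Cd4, Cd3e and Pdcd1 lie close together in the 3 libraries, while Tigit is at 8.32 in lymphoid and 70.7 in tumour cells.

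Most of the largest fold changes among abundant rows belonged to small RNA genes. The 12 largest called rises as deposited were all microRNA gene rows, led by Mir3069 and Mir5046 at 57.4 and 57.3 FPKM in the tumour library, and 9 of the 12 (Mir5046, Mir214, Mir202, Mir343, Mir23a, Mir100, Mir1898, Mir494 and Mir1932) were listed at 0 in both lymphoid libraries. Mir3069 and Mir1843b were below 0.01 FPKM there, and Mir709 was at 11.7 and 0. FPKM times annotated length put these rows at about 5 to 25 tumour fragments, which is uncertain for genes near the read length of 75 bp. For some rows tumour FPKM fell with length, from 43.6 for Mir202 (72 nt) to 38.1 for both Mir23a and Mir343 (75 nt) and 20.5 for Mir1932 (90 nt). Mir1843b (66 nt, 24.9 FPKM), Mir709 (88 nt, 88.2) and Mir214 (110 nt, 43.6) lay off this fall. Equal numbers of fragments could give values that fall in this way, so the numbers may be too high. Calls kept with counting error added rest on them, and that of Mir709 ended (adjusted p = 0.103). The 12 largest called falls as deposited were Snord43, Snord92, Snord19, Snord53, Scarna10, Snora47, Mir1949, Mir3064, Mir5136, Mir1894, Hist1h4n and Ndufs5, each under 1 estimated fragment or listed at 0 in the tumour library. With counting error added, the calls of Snord53, Snora47, Mir1894, Mir5136 and Ndufs5 ended. Snord43 was at 1050 and 671 FPKM in the lymphoid libraries. A value of 0 in these files may be a failed estimate, which was not tested. Timm8b, a mitochondrial import factor picked after its values were seen, was also listed at 0, against 13.6 and 12.9 FPKM in the lymphoid libraries. Of 107 tested snoRNA genes 63 were lower and 3 higher (median log2 change -1.21), and of 73 microRNA genes 12 were lower and 21 higher, with a median of -1.16 over all 73, in a library type made for longer RNA.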

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

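Both tests of the first pattern were chosen after the result was seen, as were the fit with counting error, the 2% trim and the cuts for short genes.

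Odorant and vomeronasal receptor genes, which T cells are not known to use and which the comparisons of genes and lists leave almost entirely aside, gave a signal in the tumour library above that in both lymphoid libraries. Their trimmed mean was 0.1521 FPKM in the tumour library against 0.013 and 0.0579 FPKM, and 0.274 against 0.0433 and 0.0897 FPKM without the trim.

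Most genes lay lower in the tumour library as deposited, by a median log2 change of -0.96. The tables argue against a few of the listed genes taking most of the fragments. The 100 most abundant held 22.9% of gene fragments in the tumour library and 27.9% and 29.8% in the lymphoid libraries. This share cannot decide the question for abundant RNA outside the rows, such as the mitochondrially encoded genes, of which 0 of 13 were listed. Fragments from outside annotated exons may contribute, since the trimmed mean of silent receptor genes was 2.63 times the higher lymphoid value. The lymphoid libraries also differed in this mean (0.013 and 0.0579 FPKM), and the one with the higher mean had the larger share in annotated genes (54.1% against 50.1%). Spread evenly over the genome, that signal would make up 40.0% of tumour fragments against 3.4% and 15.2% of lymphoid ones. Without the trim these values were 72.0% against 11.4% and 23.6%, so they depend strongly on it. Annotated genes held 22.6% of fragments against 50.1% and 54.1%, a share that falls with the FPKM values themselves and so restates the pattern. A biological difference between tumour and lymphoid cells was not tested and stays open.

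Relative to the median gene, 1246 genes were higher in the tumour library. The tables argue against an even floor as large as the trimmed silent-gene mean (0.1521 FPKM in the tumour library) as the whole cause. After that mean of each library was subtracted, 94.7% of these calls were kept. Larger or uneven background is not covered, since this floor is small beside the filter of a mean of at least 1 FPKM. Vmn2r55 and Vmn1r65, of the receptor class behind this mean, were at 44.1 and 17.1 FPKM in the tumour library. Both kept their calls after the subtraction, so it does not remove uneven signal of this class. Few fragments in the shallow tumour library may account for many of the calls, since 26.1% were kept with counting error added. That loss cannot tell the 2 apart, because a real change of this size would lose its call in the same way. The added error leaves each log2 change as it was (median 1.07 for the 1246 genes). The median SE went from 0.16 to 0.29, so that the calls ended because of the wider error. A difference between the tissues stays open for these genes and was not tested apart from handling.

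Oxidative phosphorylation genes lay lower relative to the median gene, by a median of -0.21. Transcript length may account for it, since the median lay at the 11.2 percentile of random lists matched on expression and length, against 0.1 when matched on expression alone, and 267 other short and abundant genes had a median of -0.45. Against length as a smooth trend, removing it left a median of -0.19, while camera's adjusted p went from 0.0374 to 0.152, and why that call ended was not resolved. Whether few members with failed estimates account for it cannot be told, since leaving out those under 10 estimated tumour fragments (median -0.15 for the other 64, 8.1 percentile) picks members by their tumour value and by itself moves the median towards 0. A difference in metabolism between the tissues was not tested and stays open.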

How the results depend on the processing

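Median-of-ratios scaling was foreseen, and giving its gene counts as a result of their own was decided after seeing the data. Also chosen after seeing the data were the alternatives to those gene counts, fold counts and list medians as deposited, the length, floor and counting corrections, fry on scaled values, the list without a member under 1 fragment, the trend and prior settings and the alternatives between lymphoid libraries. The shallow tumour library (6.5 fragments for a 2 kb transcript at 1 FPKM) limits every count of calls. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Without one lymphoid library no residual degrees of freedom are left, so that only values are given. DESeq2, a legacy count pipeline and voom were not run, since they need counts. As deposited, 465 genes were higher and 7620 lower, against 1246 and 899 with median-of-ratios size factors and 4333 and 275 with library totals. These counts were 109 and 4515 at a mean of at least 5 FPKM, 244 and 3998 at a minimum fold of 1.5, and 4801 and 5535 with no filter. Relative to the median gene, 1246 higher and 899 lower became 285 and 210 at a mean of at least 5 FPKM, 472 and 127 at a minimum fold of 1.5, 575 and 205 at an adjusted p under 0.01, 325 and 29 with counting error added (371 and 95, then 351 and 94, in its earlier versions), 6466 higher with no filter, and 539 lower with deposited values centred on the median gene. The 615 genes at least 2-fold higher and 276 at least 2-fold lower became 239 and 3746 as deposited, 1836 and 116 with library totals, 1885 and 479 with no filter, 181 and 126 at a mean of at least 5 FPKM, 251 and 84 with a pseudocount of 5, 335 and 76 at a fold of 3, and 545 lower with a pseudocount of 0.1. They ranged from 670 to 676 and from 336 to 338 without one lymphoid library. Camera called 4 lists as deposited, 1 with median-of-ratios size factors, 0 with those factors and without the oxidative phosphorylation member under 1 estimated fragment, 1 with library totals, 16 with no filter, 2 with a pseudocount of 0.1, 7 with a pseudocount of 5, 0 with an estimated correlation and 0 with the length trend removed. The list called with library totals was that of inhibitory receptor genes, higher. Those called with no filter were lower for pan-T-cell, Th1, naive, activation, interferon-stimulated, glycolysis, oxidative phosphorylation, cholesterol, ribosomal protein and all splicing-factor lists, and higher for macrophage, fibroblast and endothelial genes. Treg and hypoxia-response genes were called higher as deposited without ribosomal protein, histone, immunoglobulin and gene-model genes (adjusted p = 0.025 and 0.0256; adjusted p = 0.918 for both with an estimated correlation). With an estimated correlation no list call was kept under the other scalings, filters, gene classes and pseudocounts. Matched random lists called 0. Directional fry, which does not compare with other genes, called 1 as deposited (interferon-stimulated genes, lower, adjusted p = 0.03) and 0 on scaled values. Of 30 lists, 23 had a relative median above 0, against 14 as deposited, 14 with no filter and 20 to 21 without one lymphoid library. The 69 genes 2-fold apart between the lymphoid libraries became 40 at a mean of at least 5 FPKM, 147 with a pseudocount of 0.1 and 37 with a pseudocount of 5. Filters change the number of genes tested and stricter thresholds lower counts by construction, and for the other settings the cause was not tested. Of 155 named genes tested, 105 were called relative to the median gene. Calls ended for 51 of them with counting error added, 28 with no filter, 17 with centred library totals, 13 at a mean of at least 5 FPKM, 12 with centred deposited values and at most 3 in each other setting with a test, and 0 called genes turned direction. Without lymphoid replicate 1 the fold changes of 42 named genes moved by more than the spread between the lymphoid libraries, and without lymphoid replicate 2 those of 47.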

Other observations

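Among protein-coding genes in the upper 50% of expression, with transcripts of at least 500 nt and also called with counting error added and with the silent-gene mean subtracted, the 12 largest rises relative to the median gene were selected by criteria chosen after values were seen. In scaled FPKM, lymphoid cells (mean ± SD, n = 2) and the tumour library were at 1.32 ± 0.0828 and 76.2 for the vomeronasal receptor gene Vmn2r55, 0.990 ± 0.170 and 43.8 for Fosl2, a subunit of the transcription factor AP-1, and 0.559 ± 0.0308 and 26.4 for the receptor activity modifier gene Ramp3. They were at 1.05 ± 0.391 and 29.6 for Vmn1r65, 1.52 ± 0.479 and 34.7 for Crem, a cAMP-responsive transcription factor, 5.83 ± 1.80 and 87.9 for Cplx2, and 5.57 ± 1.11 and 72.4 for Grk4. Cxcr4 was at 1.81 ± 0.327 and 30.2, Vps37b at 9.29 ± 0.568 and 110.1, Aplf at 4.70 ± 1.25 and 56.4, Mid1 at 1.93 ± 0.124 and 27.8, and Rab3c at 1.68 ± 0.516 and 25.0. Vmn2r55 and Vmn1r65 belong to the receptor genes averaged above as a measure of background. Both passed these criteria, so the criteria do not remove every signal of that class. What raised them was not tested. By the same criteria 2 genes were lower, H2-T22 at 19.8 ± 0.508 and 3.33, and Amd1 at 7.11 ± 0.726 and 0.200 on about 1 tumour fragment (adjusted p = 0.0387 and 0.0102 with counting error added).

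Other genes were picked singly after their values were seen. Odc1, the first enzyme of polyamine synthesis, was at 12.0 ± 0.172 scaled FPKM in lymphoid cells and 118.3 in the tumour library, and Tnfaip3, an inhibitor of NF-kB signalling, at 14.8 ± 0.488 and 110.6, both called higher. Zbtb16, which encodes PLZF, was at 10.1 ± 0.113 and 8.56, and Klrb1c, which encodes NK1.1, at 21.9 ± 2.47 and 13.4. These 2 were not called relative to the median gene (adjusted p = 0.366 and 0.0576).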
